A study of Homo sapiens with 6 samples.

How the data were processed

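RNA of OVCAR3 cells in 6 samples, 3 labelled control and 3 labelled shIDH1, was sequenced with the QuantSeq kit for the 3' ends of mRNA, per the labels' protocols. In this assay, reverse transcription starts from the poly(A) tail and the fragment nearest to it is kept, so that a transcript gives about the same number of reads whatever its length, and a change in the poly(A) site used can move a gene's counts. The submitters' processing notes name HISAT2 2.1.0 and edgeR, and the genome builds hg38 and GRCm38, without saying which step used which; all gene identifiers were human. The counting tool, its treatment of strand and of reads that fit several genes, the annotation and any use of molecular identifiers were not given in the sources used here. Puromycin selection at 3 µg/mL lasted 7 days in all 6 libraries. Groups were taken from the sample titles. The labels do not say whether replicates of a group came from separate infections or cultures. P-values that compare libraries therefore measure the spread between these libraries, which may be technical.

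The authors deposited a table of 13802 Ensembl gene identifiers with a raw count per gene and library, in whole numbers. The deposited CPM columns equal the counts divided by the library's own total, within 0.0005, with no further scaling factor. Per the file headers, the table also holds the authors' log2 fold change, an average log2 expression, and their p-value and FDR, an adjusted p-value. Every listed gene has at least 1 count in at least 3 libraries. The totals over listed genes ranged from 557491 to 1320402 counts. Symbols were matched by identifier for 13622 genes, and 180 had none. Positions and 3' UTRs came from the GENCODE annotation of GRCh38. At a floor of 3 counts, a gene is limited to 2.27 CPM in the deepest and 5.38 CPM in the shallowest library, which covers counting error only.

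From the counts, genes with enough counts were kept (filterByExpr of edgeR 4.0.16 in R 4.3.3, minimum count 10 and minimum total 15), which left 7678. Libraries were scaled with TMM factors, and group was tested with edgeR's quasi-likelihood F test (common biological coefficient of variation 0.177), with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Levels in CPM use the library's total over the tested genes times its TMM factor. A ratio of CPM means can still differ from the fitted fold change. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and adjusted over the 26 lists with at least 5 tested members, out of 30 fixed. With the preset correlation, camera's p rests on the spread over genes and does not measure the spread between libraries. With an estimated correlation, the G1/S and G2/M lists passed and the other 6 lists that had passed did not. Single values were compared by a two-sided exact permutation test.

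The groups, the test, the 30 lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text could name the IDH genes, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 10 CPM and no overlap between groups, up to 4 called members with the smallest p per list (the member with the smallest p where none was called), and a panel of senescence and cell-cycle genes. It gave 117 genes, of which 110 were called. All 6 fits that leave out 1 library kept 67 of these. Where others are named, the libraries without which the call ended are given. ZNF485 was not tested without shIDH1 replicate 2 and was called in the other 5 fits.

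Libraries of a group were distinct, with a chi-square per degree of freedom between pairs from 2.26 to 15.0. The first principal component, with 53.9% of the variance, separated the groups. ShIDH1 replicate 3 stood apart on the second (19.5%) and had a TMM factor of 0.854, against 1.02 to 1.04 in the other libraries. It had 22.2% of its counts on the mitochondrial chromosome (95% exact binomial interval 22.1% to 22.3%). Both groups carry the replicate numbers 1 to 3 in their titles. Deviations from the group means correlated across genes at 0.116, 0.115 and 0.107 between libraries of the same number. Between libraries of different numbers the values ran from -0.0957 to -0.0248. Deviations sum to 0 within a group, so positive values for the same number force negative ones elsewhere, which are no separate evidence. On the 3 positive values the numbers were taken to pair the libraries, an assumption that was not tested further. A fit with the replicate number as a block was run beside the unblocked fit.

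The steps were tested on simulated data. With counts drawn for 7678 genes at the means and totals of this comparison, 48 of 100 genes changed 2-fold and 93 of 100 changed 4-fold were called, with the right sign, and 6 of 7478 unchanged genes were called, 4.08% of the calls. Of 200 random lists of 30 simulated genes, 6 had camera p under 0.05. These genes were simulated independently of each other, so this count does not test the preset correlation. In the data the estimated correlation was 0.593 in the mitochondrially encoded list. The alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, the replicate block, counts thinned to the smallest library, the 20 most counted genes left out of the scaling, a minimum size of 1 on the log2 scale, other list tests, and each library left out in turn. A further scaling without mitochondrial genes was added after seeing the data. For 7437 tested genes with an annotated 3' UTR, each of 15057 7-mers was scored for its association with the log2 fold change, limited to ±3, after regression on 3' UTR length, GC content and expression, and compared with 1000 permutations of the fold changes over genes. This scan used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and 241 tested genes without an annotated 3' UTR were not searched.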

Results

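OVCAR3 is an established line of high-grade serous ovarian cancer cells. The cells were infected with a control construct or with a short hairpin directed at IDH1, the cytosolic enzyme that converts isocitrate to alpha-ketoglutarate and makes NADPH, and were kept under puromycin at 3 µg/mL for 7 days before RNA was isolated. The title of the series places the comparison in work on cellular senescence, the lasting arrest of proliferation, as a treatment aim in this cancer. The 3' ends of polyadenylated RNA were sequenced from 3 control and 3 shIDH1 libraries, all from a single hairpin. Total counts were 1222186, 687247 and 768393 in control replicates 1, 2 and 3, and 1320402, 907050 and 557491 in shIDH1 replicates 1, 2 and 3. At the smallest of these totals 10 counts correspond to 17.9 CPM, counts scaled to a library total of 1000000, before any scaling factor. Levels are given as CPM on TMM-scaled totals of the tested genes, mean ± SD with n = 3 per group. Log2 fold changes are shIDH1 relative to control with the standard error (SE) of edgeR's quasi-likelihood fit and its Benjamini-Hochberg adjusted p.

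IDH1 (ENSG00000138413; GRCh38 chromosome 2, 208236227 to 208266074, minus strand) was lower in each of the 3 shIDH1 libraries than in any control library. Its level was 47.2 ± 13.5 CPM in control and 13.7 ± 5.75 CPM in shIDH1 cells (n = 3 each), a log2 fold change of -1.84 (SE 0.345, edgeR adjusted p = 0.00163), or 3.59-fold lower. The other isocitrate dehydrogenase genes did not pass the threshold. IDH2, the mitochondrial NADPH-linked enzyme, had a log2 fold change of -0.40 (SE 0.327), and IDH3A and IDH3B, subunits of the NAD-linked enzyme of the TCA cycle, had 0.33 (SE 0.223) and 0.00 (SE 0.213). IDH3G, the remaining subunit of that enzyme, had a log2 fold change of 0.88 (SE 0.310, edgeR adjusted p = 0.0559), and passed with the replicate number as a block (adjusted p = 0.0355) and without shIDH1 replicate 1 (adjusted p = 0.0155).

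**Figure D1:**
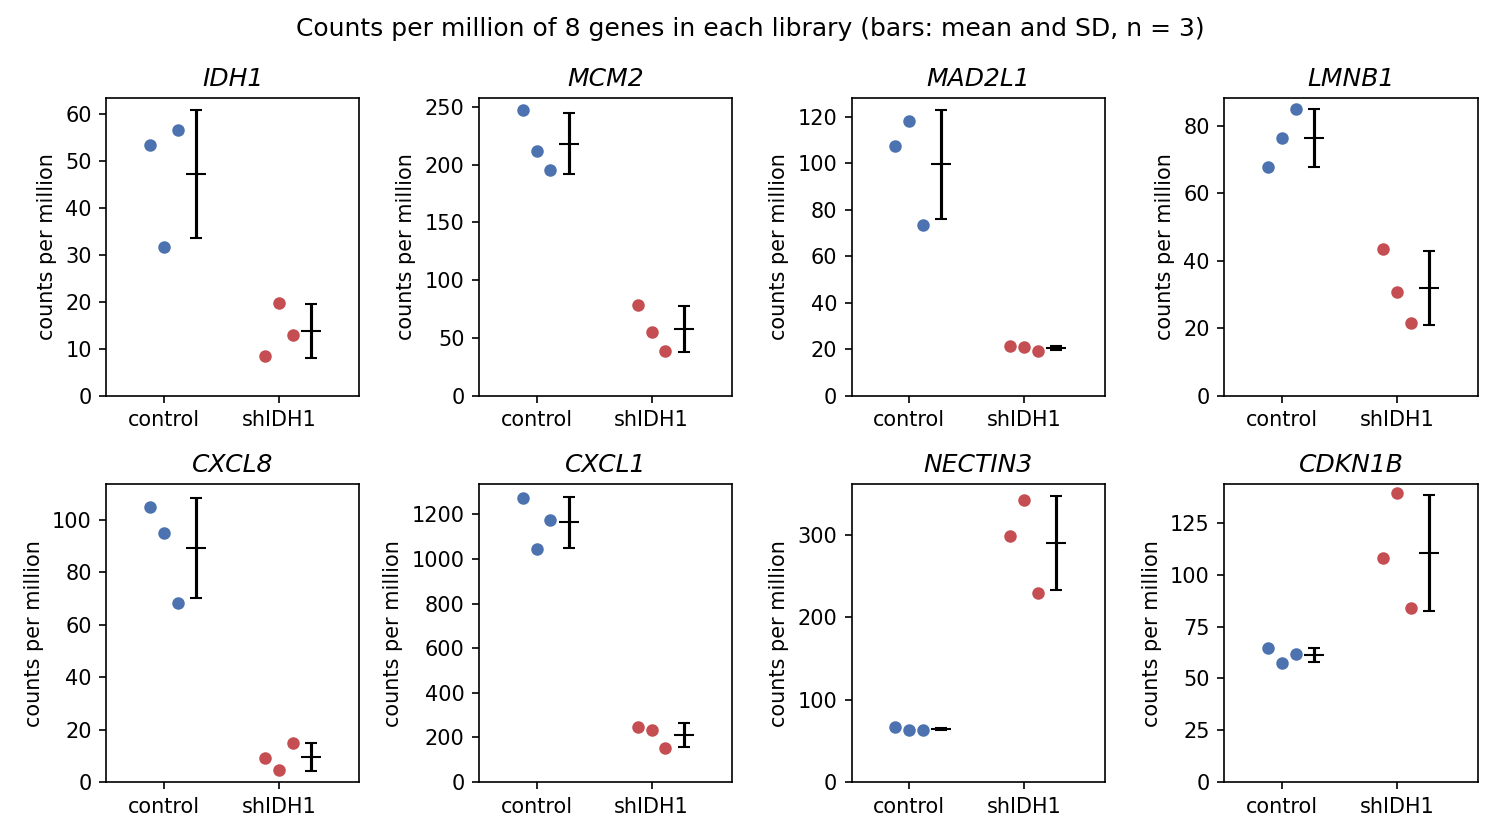
CPM (y axis, starting at 0) of 8 genes in the 3 control (blue) and 3 shIDH1 (red) libraries, 1 point per library, with the mean and SD of each group as black bars (n = 3). IDH1, MCM2, MAD2L1, LMNB1, CXCL8 and CXCL1 lie lower in every shIDH1 library than in any control library, and NECTIN3 and CDKN1B lie higher.

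Of 7678 genes tested, 1425 differed between shIDH1 and control cells, 667 higher and 758 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With sizes of at least 1 on the log2 scale, 320 were higher and 452 lower. The groups did not overlap for 1385 of the 1425 genes, and for 37.2% of all tested genes, where chance gives 10% for 3 libraries against 3. The number of genes called was 872 without control replicate 2, 679 without control replicate 3 and 821 without shIDH1 replicate 2. With library size as the only scaling, 447 genes were higher and 833 lower, so the share of higher genes went from 46.8% to 34.9%. The share of higher genes was 35.2% without control replicate 3.

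The 12 largest falls had log2 fold changes from -3.62 to -2.50. ETV4, a transcription factor of the ETS family, went from 33.1 ± 4.82 to 2.46 ± 0.502 CPM (log2 fold change -3.62, SE 0.417, adjusted p = 2.97e-05). The chemokines CXCL2 and CXCL8 had log2 fold changes of -3.56 (SE 0.455) and -3.36 (SE 0.333). AKR1B1, the aldose reductase of the polyol pathway, went from 321 ± 37.3 to 44.6 ± 11.1 CPM (log2 fold change -2.85, SE 0.229, adjusted p = 1.97e-06). EIF4EBP2, which binds the cap-binding factor eIF4E and restrains translation, fell by 2.84 (SE 0.268). CPA4 (a carboxypeptidase), PTX3 (a secreted pentraxin), GJB2 (a gap junction connexin) and RTKN2 were also among the 12 largest falls, with log2 fold changes of -3.00, -2.81, -2.78 and -2.53. The others were CDCA5, which stabilises sister chromatid cohesion (-2.51), MYBL2, a transcription factor of proliferating cells (-2.51), and the histone gene H4C3 (-2.50), whose control level of 434 ± 312 CPM varied widely. Without shIDH1 replicate 1, CXCL2, CPA4 and GJB2 had -4.31, -3.94 and -3.71. PTX3 had -3.92 without shIDH1 replicate 2, and H4C3 had -1.86 without control replicate 2. In shIDH1 replicates 1, 2 and 3, ETV4 had 4, 2 and 1 counts, CXCL2 5, 2 and 0, and CPA4 6, 2 and 0. PTX3 had 2, 5 and 0, GJB2 6, 1 and 1, and RTKN2 3, 3 and 2. So near the floor of 3 counts, the sizes and order of these falls are uncertain.

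Among the largest rises, NECTIN3, a cell adhesion molecule, went from 64.2 ± 1.73 to 290 ± 56.9 CPM (log2 fold change 2.18, SE 0.210, adjusted p = 6.97e-06). PGM2L1, which makes glucose 1,6-bisphosphate, went from 53.7 ± 11.7 to 246 ± 22.7 CPM (log2 fold change 2.22, SE 0.218, adjusted p = 7.82e-06). DEPTOR, an inhibitor of mTOR kinase, rose by 2.83 (SE 0.383), from 4.98 ± 0.874 to 36.8 ± 9.48 CPM. SULF2, an extracellular heparan sulfate sulfatase, rose by 2.90 (SE 0.460), PLXDC2 by 2.60 (SE 0.404) and ACKR2, a scavenging chemokine receptor, by 2.46 (SE 0.391). ZNF485, LINC00488 and SMIM10L2A rose by 2.44, 2.32 and 2.19. AQP11, an aquaporin, rose by 2.32, with adjusted p up to 0.0777 when control replicate 1 or control replicate 3 was left out, and a rise of 3.96 without control replicate 2. The largest fitted rise was that of UBE2D3P1 (3.18, SE 0.668), a processed pseudogene whose reads the authors' counting could have split with its parent gene, so its level is uncertain. Its shIDH1 libraries stood at 13.7, 27.5 and 94.6 CPM, and without shIDH1 replicate 3 the rise was 2.27, below those of SULF2 and DEPTOR. In control replicates 1, 2 and 3, UBE2D3P1 had 6, 2 and 3 counts, SULF2 5, 2 and 1, and PLXDC2 7, 1 and 6. ZNF485 had 3, 2 and 4, LINC00488 3, 5 and 2, and AQP11 2, 7 and 0. The sizes of these rises are therefore uncertain.

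Genes of DNA replication and mitosis were lower in shIDH1 cells. Of 36 tested members of the list of G1/S and DNA replication genes, which are largely E2F targets, 25 fell and 0 rose, with a median log2 fold change of -1.12. Of 54 tested members of the G2/M and mitosis list, 35 fell and 0 rose, with a median of -0.99, close to a 1.99-fold lower level. Adjusted over the list alone, 28 and 42 members fell. Both lists passed camera's test against the other genes (adjusted p = 1.17e-16 and 1.17e-17), and both also passed with an estimated correlation (adjusted p = 0.0201 and 0.0099). MCM2, a subunit of the replicative helicase, went from 218 ± 26.3 to 57.3 ± 19.9 CPM (log2 fold change -1.86, SE 0.233, adjusted p = 7.27e-05). FEN1, the flap endonuclease of lagging-strand synthesis, went from 180.0 ± 9.90 to 49.7 ± 2.62 CPM (-1.85, SE 0.202). DTL, a substrate receptor of the CRL4 ubiquitin ligase in S phase, fell by 2.20 (SE 0.278). MAD2L1, a component of the spindle checkpoint, went from 99.6 ± 23.4 to 20.5 ± 1.03 CPM (-2.26, SE 0.259, adjusted p = 2.97e-05), and UBE2C and BIRC5, which act in mitotic exit and chromosome segregation, fell by 1.60 (SE 0.209) and 1.58 (SE 0.216). Over both lists 60 of 90 members fell. With 1 library left out, in fits that tested other numbers of genes, the count ran from 45 without control replicate 3 to 66 without shIDH1 replicate 3, the library with the fewest counts.

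Genes reported to fall in senescent cells were lower as a group, and genes reported to rise were not higher as a group. Of 15 tested members of the first list 8 fell and 0 rose, with a median log2 fold change of -0.80 (camera adjusted p = 2.45e-06, and adjusted p = 0.101 with an estimated correlation). 3 of its tested members are also in the cell-cycle lists. LMNB1, which encodes lamin B1 of the nuclear lamina, went from 76.4 ± 8.56 to 31.9 ± 10.97 CPM (-1.16, SE 0.253, adjusted p = 0.00465). DNMT1, the maintenance DNA methyltransferase, fell by 1.57 (SE 0.211), and the histone variant gene H2AZ1 and CCNA2, cyclin A2, had log2 fold changes of -1.21 (SE 0.206) and -0.83 (SE 0.197). Adjusted over the list alone, 10 members fell. HMGB2 fell by 1.11, with adjusted p = 0.0645 without control replicate 2. In the list of genes reported higher in senescence, 2 of 11 tested members rose and 3 fell (camera adjusted p = 0.631), its median was 0.03 and its mean -0.16, and the same numbers rose and fell when adjusted over the list alone. CDKN2A, which encodes the cell-cycle inhibitor p16, was lower at 328 ± 31.3 CPM against 575 ± 38.4 in control (-0.82, SE 0.184, adjusted p = 0.0057), and PLAUR, the urokinase receptor, fell by 1.44 (SE 0.292).

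Other regulators of proliferation gave a mixed picture. CDKN1B, which encodes the inhibitor p27, rose by 0.86 (SE 0.223, adjusted p = 0.0126), a call that ended without control replicate 2, control replicate 3 or shIDH1 replicate 2, with adjusted p up to 0.0918. The proliferation marker MKI67 fell by 0.82 (SE 0.250, adjusted p = 0.0285), with adjusted p up to 0.0919 without control replicate 1, control replicate 2, shIDH1 replicate 1 or shIDH1 replicate 2. Cyclin D1 (CCND1) and cyclin E1 (CCNE1) had log2 fold changes of -0.36 (SE 0.192) and -0.38 (SE 0.212) and did not pass. CDKN1A, which encodes p21, was not tested because of low counts, with 34, 7 and 8 counts in the control and 7, 2 and 0 in the shIDH1 libraries. The interleukin gene IL6 was also below the filter, with 8 counts in all in control and 2 in shIDH1 cells.

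Secreted factors of the senescence-associated secretory phenotype (SASP) were lower in shIDH1 cells. Of 18 tested members 10 fell and 1 rose, with a median log2 fold change of -1.09 (camera adjusted p = 9.52e-05, and adjusted p = 0.0655 with an estimated correlation). Adjusted over the list alone the numbers were also 10 and 1. Without shIDH1 replicate 1 the median of the list was -0.72. The chemokine CXCL1 went from 1165 ± 114 to 210 ± 52.3 CPM (-2.45, SE 0.218, adjusted p = 5.25e-06) and CXCL8, interleukin 8, from 89.4 ± 19.02 to 9.52 ± 5.34 CPM (-3.36, adjusted p = 7.82e-06). PLAU, the urokinase plasminogen activator, fell by 2.20 (SE 0.250). The member that rose was AREG, amphiregulin (1.05, SE 0.317), named here after its value was seen. Its call ended without control replicate 2, control replicate 3 or shIDH1 replicate 2, with adjusted p up to 0.113. The list of NF-kB targets shares 3 tested members with this list, the chemokines CXCL1, CXCL2 and CXCL8, and is not independent of it. It had 6 of 14 tested members lower and 0 higher, 8 lower when adjusted over the list alone, and a median of -0.63 (camera adjusted p = 0.000268, and adjusted p = 0.0655 with an estimated correlation). TNFAIP2, outside the shared members, went from 543 ± 66.5 to 247 ± 22.1 CPM (-1.14, SE 0.189).

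Nucleotide synthesis and extracellular matrix genes were also lower as groups. In the nucleotide synthesis list 8 of 23 tested members fell and 0 rose, 9 when adjusted over the list alone, with a median log2 fold change of -0.34 (camera adjusted p = 0.0004, and adjusted p = 0.0655 with an estimated correlation). The members with the smallest p were RRM2 and RRM1, subunits of ribonucleotide reductase (-1.72, SE 0.201, and -1.24, SE 0.208), and the thymidine nucleotide kinases TK1 and DTYMK (-1.83, SE 0.237, and -1.71, SE 0.254). 5 tested members are also in the cell-cycle lists. Of 7 tested mesenchymal and matrix genes 4 fell and 1 rose, also when adjusted over the list alone, with a median of -0.999 (camera adjusted p = 0.012, and adjusted p = 0.402 with an estimated correlation). FN1, fibronectin, went from 222 ± 60.1 to 57.6 ± 29.6 CPM (-1.85, SE 0.290), and CCN1 and THBS1 had log2 fold changes of -1.21 and -1.55. The member that rose was COL6A1, a collagen VI chain (1.11, SE 0.299), named after its value was seen. Its call ended without control replicate 2, control replicate 3 or shIDH1 replicate 2, with adjusted p up to 0.0783. FBLN1, outside this list and the 1 tested marker of fibroblasts, also fell, from 21.8 ± 8.37 to 8.61 ± 5.05 CPM (-1.56, SE 0.455, adjusted p = 0.0238). Its call ended without control replicate 1, control replicate 3 or shIDH1 replicate 1, with adjusted p up to 0.157 and a log2 fold change of -0.97 without shIDH1 replicate 1.

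**Figure D2:**
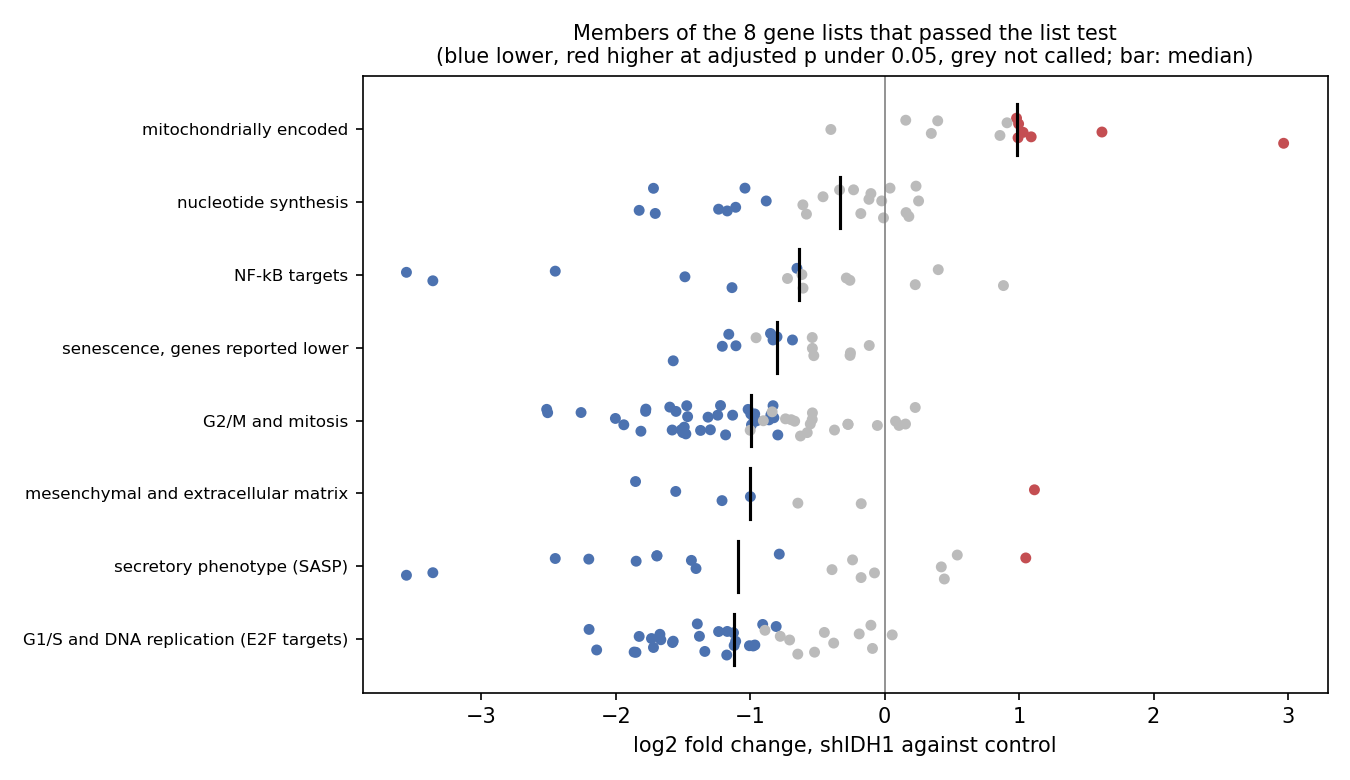
Log2 fold change of shIDH1 against control (x axis) for every tested member of the 8 lists that passed camera's test, 1 point per gene, with the list's median as a black bar. Blue and red points are genes called lower and higher at an adjusted p under 0.05, and grey points were not called. The medians run from -1.12 for the G1/S list to 0.98 for the mitochondrially encoded genes.

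The mRNAs encoded by mitochondrial DNA were the 1 list that passed with higher levels. Of its 13 protein-coding genes 7 rose and 0 fell, 9 when adjusted over the list alone, with a median log2 fold change of 0.98 (camera adjusted p = 0.000972, and adjusted p = 0.453 with an estimated correlation). MT-ND4, a subunit of respiratory complex I, stood at 11475 ± 337 CPM in control and 35181 ± 25979 CPM in shIDH1 cells (1.62, SE 0.379, adjusted p = 0.0073), with adjusted p = 0.0544 without control replicate 3. MT-ND6, also of complex I, rose by 2.97 (SE 0.558), and by 2.40 with the replicate number as a block. Its shIDH1 libraries stood at 157, 520.0 and 1726 CPM. It is encoded on the opposite strand to the other 12 genes. Whether the counting used strand was not given in the sources used here, so the level of MT-ND6 is uncertain. MT-CO1 and MT-ATP6 had 0.98 (SE 0.271) and 0.99 (SE 0.279), with adjusted p up to 0.118 for MT-CO1 without control replicate 1 or control replicate 3, and up to 0.135 for MT-ATP6 without any of the control libraries in turn. MT-CO3, chosen after its value was seen, had 0.16 (SE 0.234) and was not called. The share of counts on the mitochondrial mRNAs was 7.86% ± 0.466 in control and 13.5% ± 5.75 in shIDH1 libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Over all genes of the mitochondrial chromosome it was 9.50% ± 1.10 and 15.1% ± 6.40 (two-sided exact permutation p = 0.2). There the groups overlapped, with 10.7% in control replicate 2 and 9.83% in shIDH1 replicate 1. ShIDH1 replicate 3 alone had 19.9% on the mitochondrial mRNAs. Without this library the median of the list was 0.37 and the log2 fold changes of MT-ND6, MT-ND4, MT-CO1 and MT-ATP6 were 1.76, 0.84, 0.55 and 0.63.

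**Figure D3:**
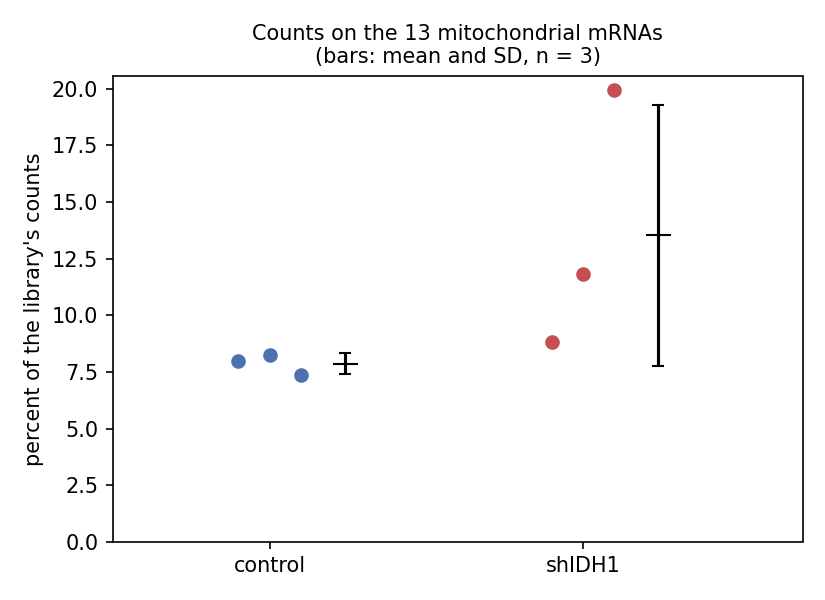
Percent of each library's counts that fell on the 13 mitochondrial protein-coding genes (y axis, starting at 0) in the 3 control (blue) and 3 shIDH1 (red) libraries, with group mean and SD as black bars (n = 3). The control libraries lie between 7.34% and 8.25% and the shIDH1 libraries at 8.80%, 11.8% and 19.9%.

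Lists of central metabolism did not pass the list test with the filter on low counts. In the TCA cycle list, 2 of 22 tested members rose and 2 fell (camera adjusted p = 0.969; 3 and 3 when adjusted over the list alone), and its median (-0.02) and mean (0.01) differed in sign. ACLY, which makes cytosolic acetyl-CoA from citrate, fell by 1.31 (SE 0.226, adjusted p = 0.000906). Of 17 tested genes of NADPH supply and the pentose phosphate pathway, 3 fell and 0 rose (adjusted p = 0.544), among them MTHFD2 (-0.76, SE 0.182), a mitochondrial enzyme of folate metabolism. In the glycolysis list 2 of 19 fell (adjusted p = 0.389; 1 when adjusted over the list alone), and in the fatty acid synthesis list 2 of 12 fell (adjusted p = 0.251, and adjusted p = 0.0475 with no filter). Nuclear genes of oxidative phosphorylation went both ways, with 4 of 52 higher and 5 lower (adjusted p = 0.544), including a rise of NDUFV2 (1.24, SE 0.225) and a fall of ATP5MC1 (-0.79, SE 0.198). Among 19 tested genes of cholesterol synthesis 4 rose and 0 fell (adjusted p = 0.251), with SC5D going from 34.4 ± 6.60 to 109 ± 12.1 CPM (1.61, SE 0.229) and SQLE rising by 1.02 (SE 0.219). In the list of NRF2 antioxidant targets 2 of 16 rose and 1 fell (adjusted p = 0.455), with a rise of 1.33 (SE 0.268) for SLC7A11, the cystine transporter.

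The following lists had camera adjusted p above the threshold with the filter on low counts. Of 14 tested genes of homologous recombination repair 5 fell and 1 rose (adjusted p = 0.0622; 7 and 1 when adjusted over the list alone). The list passed without shIDH1 replicate 3 (adjusted p = 0.011) and with no filter (adjusted p = 0.00897). RAD50 rose by 1.10 (SE 0.286), with adjusted p = 0.0721 without control replicate 1. Of 18 tested p53 targets 2 rose, among them TP53INP1 (1.07, SE 0.245), and 0 fell (adjusted p = 0.259). In the type I interferon list 2 of 19 rose and 2 fell (adjusted p = 0.0786), and the list passed without control replicate 1 (adjusted p = 0.0355) or shIDH1 replicate 1 (adjusted p = 0.0447). The ATF4 and unfolded protein response list had 6 of 28 members higher and 4 lower (adjusted p = 0.544), 9 and 5 when adjusted over the list alone. In the hypoxia list 2 of 15 rose (adjusted p = 0.662), and its median (-0.08) and mean (0.10) differed in sign. Of 17 enzymes of histone H3K9 and DNA methylation 3 fell, DNMT1 among them (adjusted p = 0.183, and adjusted p = 0.0416 with no filter). Of 24 lysosomal genes 3 rose and 3 fell (adjusted p = 0.558), with a fall of NPC2 (-1.41, SE 0.221), a cholesterol carrier, and a rise of ASAH1, acid ceramidase (1.02, SE 0.213). Of 72 genes of cytosolic ribosomal proteins 2 rose and 6 fell (adjusted p = 0.969), with median 0.05 and mean 0.00 on opposite sides of 0, and the list passed without shIDH1 replicate 3 (adjusted p = 0.0341). RPL10A (-1.26, SE 0.188) and RPL3 (-1.23, SE 0.237) were among those that fell, and because ribosomal protein genes have many processed pseudogenes their levels are uncertain.

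Lineage genes moved in both directions. Of 20 tested epithelial genes 1 rose and 3 fell (adjusted p = 0.544; 2 and 5 when adjusted over the list alone), with CDH1, E-cadherin, going from 385 ± 54.6 to 195 ± 44.7 CPM (-0.97, SE 0.206). Of 15 tested genes of the Müllerian and serous ovarian lineage 4 rose and 3 fell (adjusted p = 0.267; 5 and 4 when adjusted over the list alone). CD24, CP (ceruloplasmin) and MSLN (mesothelin) rose by 1.06 (SE 0.188), 1.30 (SE 0.250) and 1.25 (SE 0.277), and SOX17, a transcription factor, fell by 0.96 (SE 0.215). Of the markers of other cell types, 1 of 12 fibroblast, 0 of 15 leukocyte and 1 of 11 endothelial markers passed the filter on low counts. These were FBLN1, which fell, and ERG, the endothelial marker, which stood at 17.1 ± 2.91 CPM in control and 21.1 ± 6.49 CPM in shIDH1 cells (0.28, SE 0.330). Of 17 genes of MHC class I antigen presentation 3 could be tested, too few for a list test, and CALR, calreticulin, fell by 0.85 (SE 0.204).

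The authors' deposited table gave 1725 genes an adjusted p under 0.05, 781 higher and 944 lower, and IDH1 had a log2 fold change of -1.85 with an adjusted p of 1.65e-05. Of the 1425 genes called here 1354 were among them with the same sign and 0 with the opposite sign, and 71 were called here alone. Of the others in the authors' deposited table, 95 were tested here and not called, and 276 were below the filter on low counts.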

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

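The fall of IDH1 kept its direction and passed the threshold under every alternative, with log2 fold changes from -2.26 to -1.46. The 1425 genes called (667 higher, 758 lower) became 772 (320 higher, 452 lower) with a minimum size of 1 on the log2 scale, which the added condition explains. With DESeq2, 444 were higher; the cause was not tested. Leaving out 1 library gave 679 to 1564 genes, 239 to 743 higher and 426 to 821 lower; smaller groups lower the power, but the differences between left-out libraries were not traced. The other scalings, filters and tests, counts thinned to the smallest library and the scaling without mitochondrial genes, chosen after seeing the data, stayed within 1.5 times each count. The replicate block gave 1793 genes, 1423 of them among the 1425; it moved IDH3G past the threshold, turned the direction of the TCA cycle list, which was not called, and changed no other call of a named gene or list.

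All 8 gene lists passed under the alternatives run for them, except other list tests; DESeq2, limma-voom, the likelihood ratio test and the minimum size were not run for lists. With no filter 11 passed, and with an estimated correlation 2 passed. Adjusted p with an estimated correlation was 0.453 for mitochondrially encoded genes, 0.101 for genes reported lower in senescence, 0.402 for mesenchymal and matrix genes, and 0.0655 for each of SASP, NF-kB targets and nucleotide synthesis. This form also uses the residual degrees of freedom. For SASP, NF-kB targets and nucleotide synthesis the estimated correlations were -0.0322, -0.00033 and -0.0294, below the preset 0.01. These values argue against a higher correlation as the reason these lists no longer passed. The estimates were 0.593 for mitochondrially encoded genes, 0.263 for mesenchymal and matrix genes and 0.0966 for genes reported lower in senescence, where the cause was not tested. With fry, which does not compare a list with other genes, 14 passed, 7 of them in common, and mitochondrially encoded genes did not (adjusted p = 0.169). The TCA cycle list, not called, reversed direction with library size only (adjusted p = 0.958), no filter (0.805), a mean of at least 10 CPM (0.977), the replicate block (0.987), thinned counts (0.948) and fry (0.944), and had adjusted p from 0.832 to 0.998 over the fits without 1 library. The hypoxia list reversed with no filter (adjusted p = 0.961). Without 1 library, the ribosomal protein list had adjusted p from 0.0341 to 0.996 and the log2 fold change of IDH3B ran from -0.084 to 0.095, both with changes of sign. The cause of these reversals was not tested.

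Over the named genes, 1353 of 1391 results under alternatives other than leaving out a library kept their direction and side of the threshold, 36 fell short of it and 2 newly passed. Leaving out 1 library kept 589 of 701, with 107 falling short. Depth limits genes near the filter: without scaling factors, 10 counts are 7.57 CPM in the deepest and 17.9 CPM in the shallowest library. A 2-fold change was called for 48 of 100 simulated genes.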

Other observations

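The tests of the 7-mer AAGTCTC other than the share of fallen genes that have it, the test of a shared rise of the mitochondrial mRNAs, the fit of the mitochondrial list without shIDH1 replicate 3, the test of cell-cycle members without the 7-mer, and the splits fitted with the replicate block were chosen after the results they bear on, or values close to them, had been seen. In edgeR's test without the block, 1425 genes were called for the real grouping and 0 for each of the other 9 splits of the 6 libraries into 3 and 3. Those 9 splits had 64 to 358 genes at an unadjusted p under 0.05, against 2557. Of the 10 splits 1 gave as many genes. Since the numbers were taken to pair the libraries, the real grouping compares with the 3 other splits that also part all 3 replicate numbers; the remaining 6 part 1 number each. With the replicate block, edgeR called 1793 genes for the real grouping and 0 for each of these 3, which had 15 to 59 genes at an unadjusted p under 0.05, against 2753. Among the 4 splits that part all 3 numbers the share cannot go under 0.25, too few for a share under 0.05. Each split other than the real one puts control and shIDH1 libraries on both sides. A difference between the groups then adds to the spread within a side and makes calls rare. With or without the block, the 0 calls of these splits therefore carry little weight on whether the grouping arose by chance.

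The fall of the cell-cycle lists was set against 3 technical explanations. With 1 library left out, in fits that tested other numbers of genes, 45 to 66 of their members fell, 66 without the shallow shIDH1 replicate 3, which argues against that library alone as the source. After regression on 3' UTR GC content, 3' UTR length and expression the median log2 fold change of the 90 members was -0.98, which argues against these trends as the whole cause. The 87 members whose 3' UTR lacks the 7-mer AAGTCTC had a median of -1.01, so matches to it do not account for the fall. A response to lower IDH1 and off-target effects of the hairpin that act through other genes both stay open and were not tested, since the libraries come from 1 hairpin.

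The rise of the mitochondrial mRNAs was uneven. A loss of cytoplasmic RNA would raise all 13 genes alike. Their log2 fold changes ran from -0.40 to 2.97, and Cochran's Q from the fitted standard errors was 42.5 on 12 degrees of freedom (95th percentile of chi-square 21). The extremes were MT-ATP8, at 4350 ± 3433 CPM in control, and MT-ND6, whose treatment by strand is unknown. How reads that fit several genes were counted was not given either. Q therefore cannot tell unequal transcripts from unequal counting, and it leaves this loss open. How far the pattern rests on shIDH1 replicate 3 stays open: without it the median of the list was 0.374, against 0.98, a value that lies between what that library alone and a shared rise would give. No biological explanation was tested beyond the grouping by hairpin.

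A hypothesis concerns the hairpin itself. Short hairpins can lower transcripts that match positions near the 5' end of their guide strand in the 3' UTR. Among 15057 7-mers, AAGTCTC had the strongest association with lower log2 fold changes (z = -8.25, the next 7-mer -5.89, and 5th percentile of the lowest z over 1000 permutations -4.53), and z ran from -8.35 to -7.76 without 1 library. The 836 genes with it had a median log2 fold change of -0.11, against 0.03 in the others, an adjusted difference of -0.20 (SE 0.024). It lies in the coding sequence of IDH1, in exon 9 of 10 (GRCh38 chromosome 2, 208239137 to 208239143, minus strand). That match carries little weight alone, since 16.0% of the scanned 7-mers occur in an IDH1 transcript, as do 8 of the 17 7-mers past the permuted limit. These values are consistent with a seed match of the hairpin (z = -8.25), whose sequence was not used here.

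The lowest z of the 20 scanned 7-mers that differ from AAGTCTC in 1 base was -5.48. This is weaker than that of AAGTCTC but past the permuted limit of -4.53. A changed base also changes the composition, so these 7-mers cannot decide on base composition. Some of the lowest 7-mers share GTCTC with it, among them TGTCTCT (z = -5.89) and AGTCTCA (z = -5.81). A trend over such related sequences was not tested. Against Alu repeats, z of AAGTCTC was -7.77 without the 525 genes that hold an Alu-like stretch. In the last 500 bases of the 3' UTR alone z was -4.83, with 189 genes, past the 5th percentile of -4.43 over 100 permutations, but 1 other 7-mer had a lower z there. Passing a permuted limit carries little weight alone, since TTTTTTT, found in 4113 genes, passed that of the full 3' UTR (z = -5.83). The effect, if real, is small and could not account for most calls: 14.96% of the genes that fell have the 7-mer, against 9.54% of those that rose and 10.96% of those not called. AKR1B1 and EIF4EBP2, among the 12 largest falls, have it, and so do SULF2 and PLXDC2, among the 12 largest rises.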
